A study of Homo sapiens with 28 samples.

How the data were processed

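The study measured RNA in A549 and H1944 lung adenocarcinoma cells that carried the MGT#1-mVenus reporter, in 28 libraries made with a stranded total RNA kit for low input, per the labels. Each library is a gate or an unsorted naive culture with a replicate letter. The deposited table holds 1 integer count per gene and library; the authors demultiplexed with bcl2fastq 2.20.0, aligned to GRCh38 with STAR 2.6.0c and counted reads per gene with HTSeq 0.12.3, per the submitters' processing notes. Whether reads were trimmed or duplicates removed was not given in the sources used here. Total counts ran from 1660148 to 13280592 per library. Without molecular identifiers, reads that arose by PCR count as separate reads, so counting intervals and floors cover counting error only.

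The table had 60487 rows, of which 60483 carried an Ensembl gene identifier and 4 named reporter sequences. Symbols were found for 56321 identifiers, and biotypes and coordinates came from GENCODE 29. The mVenus row stayed in the fits and was left out of counts of changed genes, because the gates were set on it. The other reporter rows held at most 1 count in any library. Levels are CPM values computed from the deposited counts and each library's total, without TMM factors.

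Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests, with TMM normalization and edgeR's own filter on low counts, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Each line was fitted by itself with its 5 groups as the model, and contrasts against naive cells took the mean of both gates. This fit took each library as independent, although gates of a letter may share a culture. Values of n count libraries, and an SD over both gates also holds the difference between the gates. Differences between the lines came from a fit of both. The filter kept 19842 genes in A549, 13621 in H1944 and 17918 in the joint fit. The common biological coefficient of variation was 0.358 in A549 and 0.0978 in H1944, with 8 and 10 residual degrees of freedom. The 16 comparisons, the groups, the filter, the test and 33 gene lists were fixed before the data were examined.

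Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. Of 1268 list entries 1264 matched a gene, and a list needed 5 tested members, which left 32 lists in A549 and 29 in H1944. The number of members past the test is given over all genes and again adjusted over the list alone.

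Genes named in the text follow a rule: in the 8 main comparisons the 8 highest and 8 lowest protein-coding genes by log2 fold change past the test, with a mean of at least 2 CPM and arms that do not overlap, the 4 members of smallest adjusted p of each list, and 11 key genes of epithelial and mesenchymal identity. In the other comparisons these numbers were 5, 5 and 2. Where an arm held 0 counts, the fold is a lower bound from a floor of 3 counts over the arm. Where it held 1 to 3 counts the ratio of CPM is given with an exact 95% counting interval. For some folds on 4 to 10 counts this interval is given beside the SE. On arms of so few counts an SE can be smaller than counting error alone allows, and it then understates the uncertainty.

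Silent olfactory receptor genes served as a measure of background reads: 374 were summed, and 2 with a group mean of at least 5 CPM were left out. This measure, and 150 CPM as the level above which 2 A549 libraries were set aside in an alternative, were chosen after the data were seen. The letters were checked for pairing by the correlation of deviations from group means. Between the gates of H1944 under GSK126 the same-letter values were 0.148, 0.235 and 0.191, so the letters were taken as pairs there, from the data and not from the labels. Same-letter gates of A549 had values from 0.08 to 0.52 and were not taken as pairs, but pairs are not excluded there.

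The alternatives were RLE size factors, no filter and a filter at 1 CPM, DESeq2 1.42.0, limma-voom with sample weights, fits of the compared groups alone or of all 28 libraries, blocks by replicate letter, each gate alone against naive cells, and each library left out in turn. Alternatives added later were coding genes of at least 5 CPM, the background as a covariate, and the fit without the 2 background-rich libraries. Regroupings of the same libraries, at most 100 per result, gave the counts to be had by chance. For a difference between 2 effects they could also remove the effects themselves, so they could not decide that question. Where they moved the paired H1944 GSK126 libraries, only regroupings that parted as many pairs as the real one were used: all 3 between the gates and 0 elsewhere. The test was tried on simulated counts with the spread of each fit, in which genes were changed 1.5-fold, 2-fold or 4-fold. Camera found a list raised 1.5-fold in such counts for the H1944 gates under GSK126, the only comparison in which it was tried. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

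The third A549 libraries of the high GSK126 and the low TGF-β1 gate were not analysed here. Some genes that the rule names are not reported here. Splicing, sequence variants and the raw reads were not analysed here.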

Results

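Transcript counts were obtained for 28 RNA libraries of 2 human lung adenocarcinoma lines, 13 of A549 and 15 of H1944. Both lines carried MGT#1-mVenus, a synthetic reporter designed to read out a mesenchymal state, which drives the fluorescent protein mVenus. Cells were exposed for 11 days either to GSK126 at 5 µM, an inhibitor of the histone methyltransferase EZH2 that places the repressive mark H3K27me3, or to TGF-β1 at 5 ng/ml, a cytokine that induces epithelial-mesenchymal transition. Each treated population was separated by flow sorting into a gate of high and a gate of low mVenus fluorescence. Naive cells were sequenced unsorted. A549 had 3 libraries of the low and 2 of the high gate under GSK126, 2 of the low and 3 of the high gate under TGF-β1, and 3 naive libraries. H1944 had 3 libraries in each of the same 5 groups. A549 library C of the high GSK126 gate and library B of the low TGF-β1 gate were not analysed here. Total counts ran from 2013449 to 9550143 in A549 (median 4783344) and from 1660148 to 13280592 in H1944 (median 2552121).

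The reporter transcript followed the gates in both lines. In H1944 mVenus stood at 2346 ± 82.5 CPM (SD, n = 3) in the high and 791 ± 34.3 CPM (n = 3) in the low TGF-β1 gate. It stood at 859 ± 49.2 CPM (n = 3) in the high and 243 ± 35.9 CPM (n = 3) in the low GSK126 gate, beside 356 ± 34.5 CPM (n = 3) in naive cells. In A549 it stood at 2476 ± 637 CPM (n = 3) in the high and 1066 ± 97.6 CPM (n = 2) in the low TGF-β1 gate. Under GSK126 it was at 1580 ± 489 CPM (n = 2) in the high and 893 ± 182 CPM (n = 3) in the low gate, and in naive cells at 478 ± 18.8 CPM (n = 3). Between the A549 gates it did not pass the test over all genes, with log2 fold changes of 1.02 ± 0.33 (SE; unadjusted p = 0.00563) under GSK126 and 1.25 ± 0.34 (unadjusted p = 0.00169) under TGF-β1. Since the gates were set on this protein, the reporter served as a check of the labels and was left out of every count of changed genes.

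**Figure D1:**
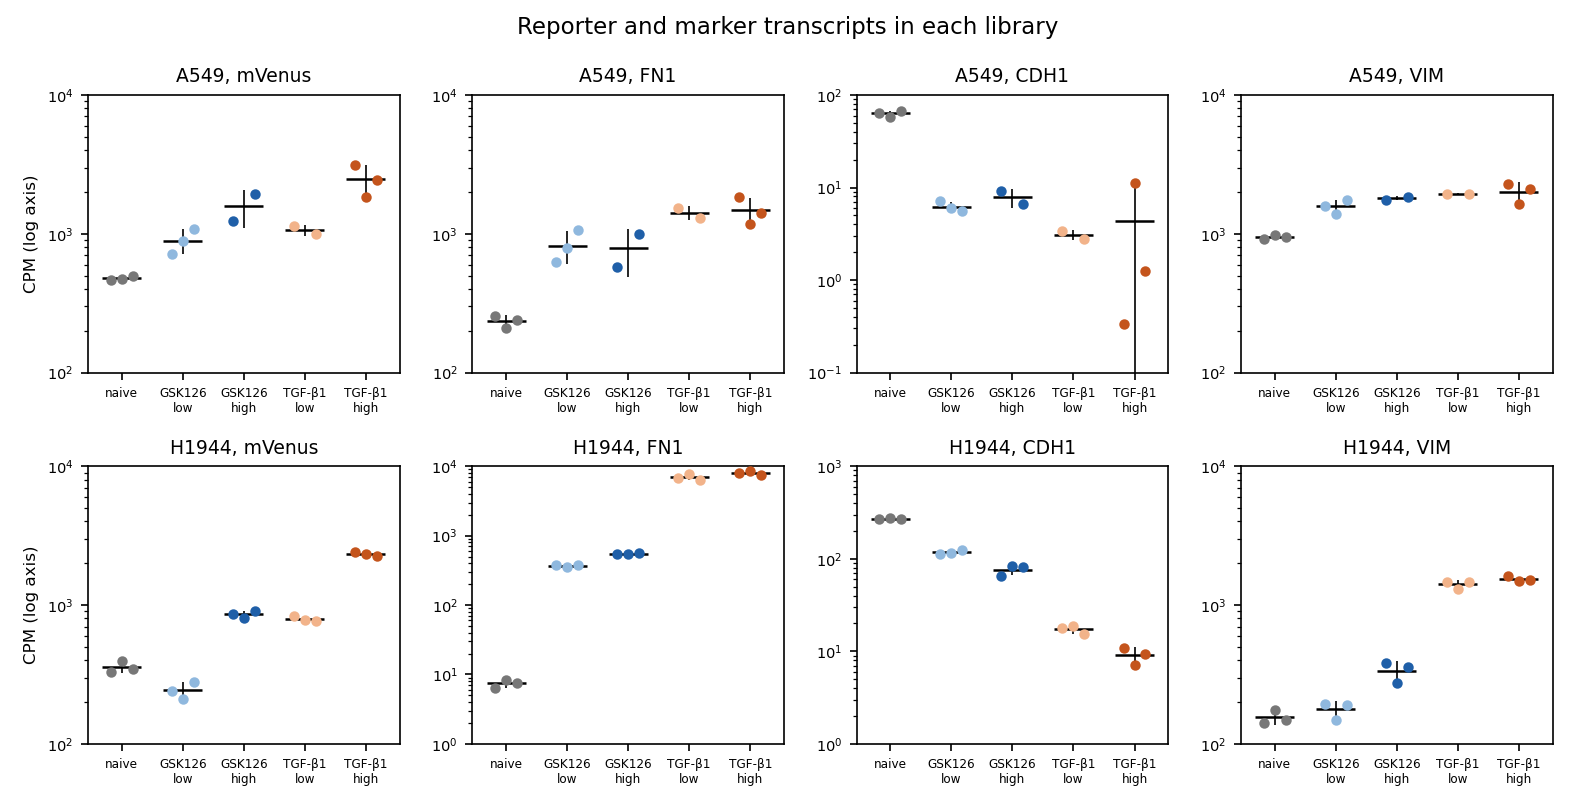
Levels (CPM) of the mVenus reporter and of 3 marker genes in each library of A549 (upper panels) and H1944 (lower panels). Points are libraries, horizontal bars are group means and vertical bars are 1 SD, on log axes that differ between panels. CDH1 lies lower, and FN1 lies higher, in all treated libraries than in the naive libraries of the same line.

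The comparison of GSK126 with naive cells asked which genes changed on prolonged EZH2 inhibition. In A549, GSK126 raised mesenchymal and TGF-β-responsive genes, and 8 of 37 epithelial genes fell. FN1, the gene of the matrix protein fibronectin, rose from 234 ± 23.5 CPM (SD, n = 3) to 809 ± 218 CPM (n = 5), a log2 fold change of 1.72 ± 0.28 (SE). The EMT transcription factor SNAI2 (4.89 ± 0.36), the osteogenic factor RUNX2 (4.54 ± 0.33), the mesenchymal regulator FOXC2 (4.47 ± 0.63) and the chemokine receptor ACKR3 (5.08 ± 0.50) rose with it. CDH1, the gene of E-cadherin (chromosome 16, 68737225 to 68835548), fell from 63.3 to 6.88 CPM (−3.24 ± 0.45), and the death ligand TNFSF10 (−5.79 ± 0.69) and the bile acid enzyme BAAT (−4.02 ± 0.30) also fell. CD44 (1.13 ± 0.23) and CDH2 (0.91 ± 0.22) rose, whereas VIM (0.75 ± 0.24), EPCAM (−0.85 ± 0.28), ZEB1 (0.48 ± 0.19) and EZH2 itself (0.19 ± 0.21) did not pass the test.

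Of 29 tested mesenchymal genes in A549, 15 rose and 0 fell under GSK126 (18 and 1 adjusted over the list alone). Among them were DPYSL3 (3.98 ± 0.24), the receptor tyrosine kinase AXL (from 60.5 to 508 CPM) and tenascin C, TNC (2.30 ± 0.22). This list stood above the other genes by camera (adjusted p = 7.97e-33), with an adjusted p = 0.00235 with an estimated correlation. TGF-β target genes rose in 13 of 34 and fell in 2 (17 and 2 adjusted over the list alone; camera adjusted p = 1.41e-26, and adjusted p = 0.0485 with an estimated correlation). LTBP2 (3.88 ± 0.28) and ADAM19 (4.07 ± 0.33) are examples. YAP and TEAD target genes rose in 16 of 28 and 0 fell (21 and 1 adjusted over the list alone; adjusted p = 8.96e-28, and adjusted p = 0.0485 with an estimated correlation). CCN1 (2.97 ± 0.26) was among them. Among collagens, laminins and matrix enzymes 17 of 51 rose and 4 fell (19 and 5 adjusted over the list alone; adjusted p = 3.51e-08, but adjusted p = 0.0737 with an estimated correlation). FBN2 (3.16 ± 0.27) rose, and the basement membrane collagens COL4A3 (−2.56 ± 0.23) and COL4A4 (−1.82 ± 0.18) fell. Fibroblast markers rose in 2 of 14 and 0 fell, with the same numbers adjusted over the list alone (median −0.06; adjusted p = 0.00714, but adjusted p = 0.387 with an estimated correlation). Of 37 epithelial genes 8 fell and 1 rose (11 and 4 adjusted over the list alone; adjusted p = 0.00187, but adjusted p = 0.0628 with an estimated correlation). JUP (−1.82 ± 0.29), ELF3 (−1.40 ± 0.19) and KRT18 (−1.28 ± 0.24) were among them. Gut and liver genes fell in 9 of 26 with no rise (10 and 0 adjusted over the list alone; adjusted p = 1.09e-07, but adjusted p = 0.236 with an estimated correlation). The urea cycle gene CPS1 (−1.99 ± 0.20) was among them. Cholesterol synthesis genes rose in 8 of 31 with no fall (11 and 0 adjusted over the list alone; adjusted p = 7.22e-08, but adjusted p = 0.387 with an estimated correlation). INSIG1 (1.88 ± 0.30) was among them.

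Ribosomal protein genes fell in 9 of 75 with no rise (21 and 0 adjusted over the list alone; camera adjusted p = 2.19e-13, but adjusted p = 0.424 with an estimated correlation). Their median log2 change was −0.55, where the median of all genes was −0.16. Mitochondrially encoded genes fell in 6 of 15 with no rise (11 and 0 adjusted over the list alone; adjusted p = 1.09e-08, but adjusted p = 0.0615 with an estimated correlation). The mitochondrial share of counts was 7.60 ± 1.53% (SD, n = 3) in naive A549 libraries, 5.39 ± 0.177% (n = 3) in the low and 5.01 ± 0.432% (n = 2) in the high GSK126 gate. In total 1363 of 19842 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 726 higher and 637 lower. The count was 676 without the GSK126 high library B, 871 without the naive library B and 873 with the low gate alone, and it was 2281 with DESeq2 and 3412 with limma-voom. Treated cells were sorted and naive cells were not, so every comparison with naive cells holds the effect of sorting as well.

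TGF-β1 changed A549 more widely. The secreted and matrix genes COL5A1 (8.14 ± 0.44), COL22A1 (7.66 ± 0.46), the metalloprotease ADAM19 (7.77 ± 0.38) and the cytokine IL11 (7.64 ± 0.34) rose. The mucins MUC5AC (−9.12 ± 0.51) and MUC5B (−9.34 ± 0.54) fell. The mucin-folding protein AGR2 (from 1121 to 2.10 CPM, −9.24 ± 0.41), the antioxidant enzyme GPX2 (−8.56 ± 0.30) and the fibrinogen chains FGA (−7.02 ± 0.63) and FGB (−8.20 ± 0.61) fell too. CDH1 fell from 63.3 to 3.82 ± 4.36 CPM (SD, n = 5; −4.35 ± 0.46), EPCAM fell (−1.53 ± 0.27), and CDH2 (2.52 ± 0.24), FN1 (2.49 ± 0.29), SNAI2 (4.93 ± 0.36), ZEB1 (0.91 ± 0.19) and VIM (0.90 ± 0.24) rose. EZH2 fell by 0.83 ± 0.21 on the log2 scale.

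TGF-β target genes rose in 28 of 34 and fell in 1 (28 and 2 adjusted over the list alone; camera adjusted p = 5.42e-55, and adjusted p = 0.00794 with an estimated correlation). Mesenchymal genes rose in 21 of 29 and fell in 2 (23 and 2 adjusted over the list alone; adjusted p = 2.27e-27, and adjusted p = 0.00706 with an estimated correlation), with MMP2 (5.08 ± 0.35) and CDH11 (6.46 ± 0.45) among them. Of 51 collagens, laminins and matrix enzymes 24 rose and 4 fell (26 and 6 adjusted over the list alone; adjusted p = 0.0196 with an estimated correlation). Of 20 integrins 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0213 with an estimated correlation). ITGA11 (6.78 ± 0.34) was among them. Epithelial genes fell in 16 of 37 and rose in 3 (16 and 4 adjusted over the list alone; adjusted p = 0.00706 with an estimated correlation). CLDN2 (−4.71 ± 0.22) and KRT19 (−3.96 ± 0.22) were among them. Lung alveolar and secretory genes fell in 8 of 24 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0147 with an estimated correlation). Gut and liver genes fell in 11 of 26 and rose in 1 (11 and 2 adjusted over the list alone; median −0.09; adjusted p = 3.39e-07, but adjusted p = 0.150 with an estimated correlation). Fibroblast markers rose in 6 of 14 and fell in 1, with the same numbers adjusted over the list alone (median 1.12; adjusted p = 2.06e-04, but adjusted p = 0.150 with an estimated correlation). Genes of DNA synthesis and division fell nearly throughout, and 0 rose. Proliferation genes fell in 55 of 60 (58 adjusted over the list alone; median −1.12; adjusted p = 5.51e-23, but adjusted p = 0.193 with an estimated correlation). Replication-dependent histone genes fell in 43 of 45 (43 adjusted over the list alone; median −1.97; adjusted p = 1.44e-41, but adjusted p = 0.0881 with an estimated correlation). NRF2 targets, the antioxidant programme that is constitutively active in A549, fell in 26 of 31 and rose in 1 (27 and 1 adjusted over the list alone; adjusted p = 2.27e-27, but adjusted p = 0.106 with an estimated correlation). AKR1B10 (from 6472 to 417 CPM, −4.10 ± 0.28) and ALDH3A1 (−3.55 ± 0.26) were among them. Ribosomal protein genes fell in 37 of 75 (53 adjusted over the list alone; adjusted p = 1.37e-09, but adjusted p = 0.608 with an estimated correlation). The mitochondrial share of counts was 6.44 ± 0.233% (n = 2) in the low and 6.27 ± 0.424% (n = 3) in the high gate.

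In total 3821 of 19842 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05 in A549 under TGF-β1, 1542 higher and 2279 lower. The count was 2433 with the low gate alone and 7887 with limma-voom. Reads over silent olfactory receptor genes, a measure of background, were uneven in A549. They reached 305 CPM in library B of the high TGF-β1 gate and 195 CPM in naive library A. CDH1 stood at 11.3 CPM in that TGF-β1 library against 0.333 and 1.26 CPM in the other libraries of its gate.

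**Figure D2:**
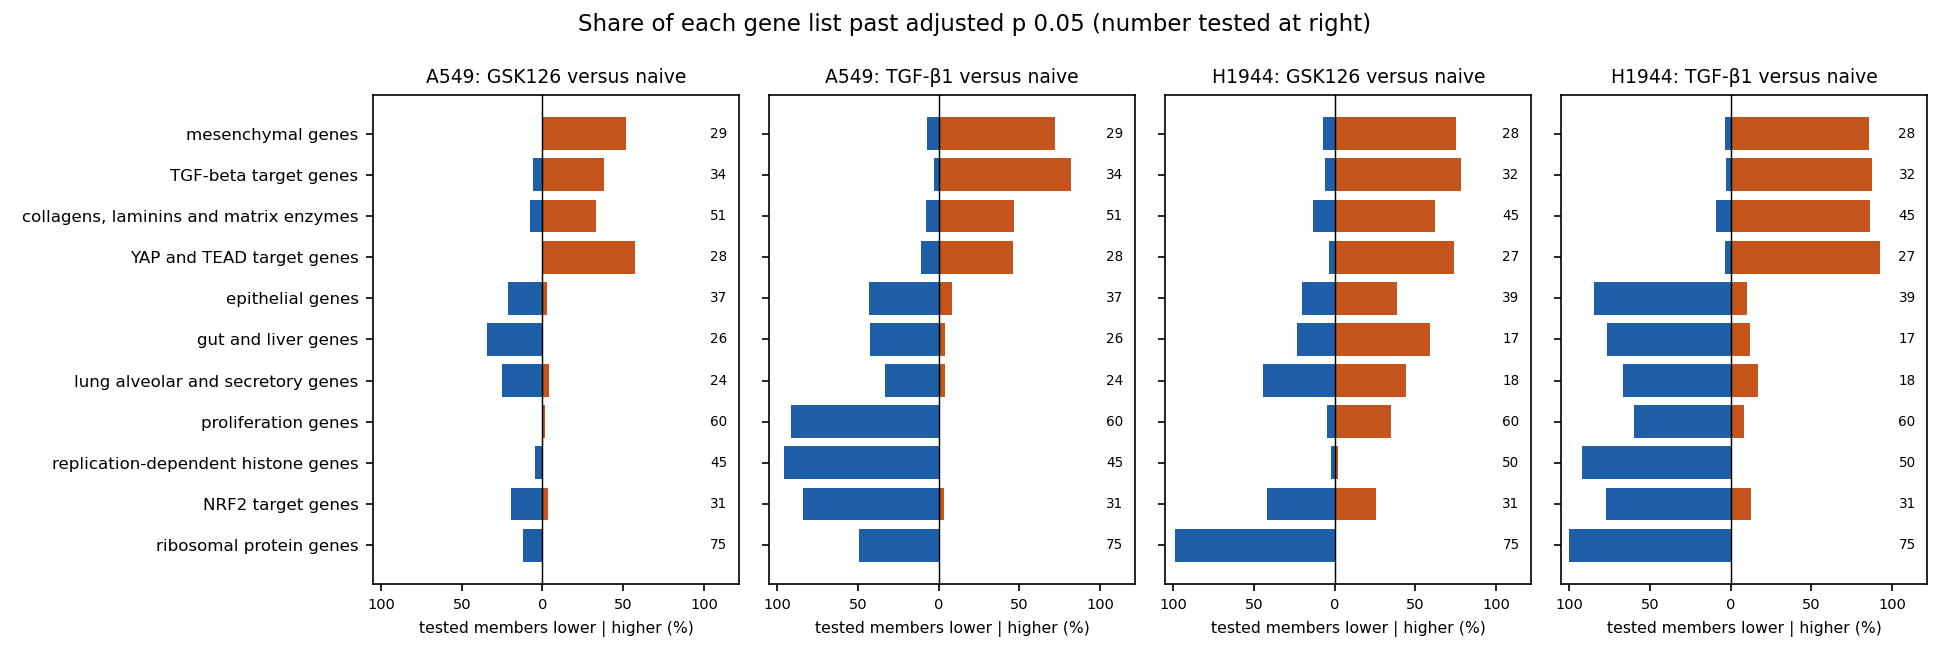
Share of the tested members of 11 fixed gene lists that were lower (blue, left) or higher (orange, right) than in naive cells at an adjusted p of 0.05, as a percentage of the members tested, whose number stands at the right of each panel. Under TGF-β1 in H1944, 33 of 39 epithelial genes were lower; under GSK126, 8 were lower and 15 higher.

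In H1944, GSK126 also raised mesenchymal and TGF-β-responsive genes, while epithelial genes moved both ways. Fibronectin, FN1 (chromosome 2, 215360440 to 215436172), rose from 7.41 ± 1.02 CPM (SD, n = 3) to 458 ± 97.8 CPM (n = 6 libraries, in 3 same-letter pairs of gates; 5.78 ± 0.12). CDH2 (3.04 ± 0.16), SNAI2 (5.10 ± 0.41) and VIM (0.55 ± 0.10) rose. REG1A (7.65 ± 0.28), a secreted regenerating protein, was among the highest, as was the teneurin TENM3. The 3 naive counts of TENM3 stood against 1578 (ratio 471, 95% counting interval 161 to 2286). REG1A had 7 naive counts (ratio 252.4, interval 122.3 to 628.5) and SNAI2 had 5 (ratio 41.9, interval 17.7 to 130.3). The SE of REG1A and SNAI2 understates the uncertainty. CDH1 fell from 271 to 97.3 CPM (−1.64 ± 0.09), CD44 (−0.78 ± 0.07) and ZEB1 (−0.42 ± 0.13) fell. The lowest genes included the fibrillin FBN1 (from 349 to 27.6 CPM), the liver glycogen synthase GYS2 (−3.63 ± 0.13) and the histidine ammonia-lyase HAL (−3.71 ± 0.14). EZH2 rose slightly (0.27 ± 0.10), and EPCAM did not pass the test (0.16 ± 0.12).

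Mesenchymal genes rose in 21 of 28 and fell in 2 in H1944 under GSK126, with the same numbers adjusted over the list alone (camera adjusted p = 1.98e-15, and adjusted p = 0.0208 with an estimated correlation). TGF-β target genes rose in 25 of 32 and fell in 2 (27 and 2 adjusted over the list alone; adjusted p = 4.44e-15, and adjusted p = 0.0308 with an estimated correlation). CCN2 (2.66 ± 0.12) and the ligand gene TGFB2 (4.74 ± 0.25) were among them. YAP and TEAD target genes rose in 20 of 27 and fell in 1 (20 and 1 adjusted over the list alone; adjusted p = 2.95e-13, but adjusted p = 0.0747 with an estimated correlation). CCN1 (3.13 ± 0.12) was among them. Collagens, laminins and matrix enzymes rose in 28 of 45 and fell in 6 (30 and 7 adjusted over the list alone; adjusted p = 2.38e-06, but adjusted p = 0.124 with an estimated correlation), with COL12A1 (5.12 ± 0.15) rising. Of 39 epithelial genes 15 rose and 8 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.241): CLDN2 (4.48 ± 0.25), MUC1 (1.24 ± 0.11) and CLDN1 (1.23 ± 0.12) rose while CDH1 fell. Antigen presentation genes of MHC class I rose in 11 of 20 with no fall, likewise adjusted over the list alone (adjusted p = 5.58e-05, but adjusted p = 0.104 with an estimated correlation). HLA-B (2.66 ± 0.12) was among them. Cancer-testis genes, which are silent in most somatic cells, rose in 9 of 12 with no fall, also adjusted over the list alone (adjusted p = 1.25e-04, but adjusted p = 0.107 with an estimated correlation). MAGEA10 (2.65 ± 0.19) and MAGEC2 (3.16 ± 0.34) were among them. NF-kB and inflammatory genes rose in 28 of 40 and fell in 4 (29 and 4 adjusted over the list alone; adjusted p = 4.86e-05, but adjusted p = 0.343 with an estimated correlation). Fibroblast markers rose in 6 of 11 and 0 fell (8 and 0 adjusted over the list alone; median 2.40; adjusted p = 0.00456, but adjusted p = 0.275 with an estimated correlation). IL32 (2.97 ± 0.20) rose among the inflammatory genes, and S100A8 (−3.35 ± 0.17) and S100A9 (−2.10 ± 0.08) fell.

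Ribosomal protein genes fell in 74 of 75 in H1944 under GSK126 (74 adjusted over the list alone; median −0.67; camera adjusted p = 1.93e-25, but adjusted p = 0.164 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 15 (12 adjusted over the list alone; adjusted p = 7.44e-04, but adjusted p = 0.289 with an estimated correlation). The mitochondrial share of counts was 6.95 ± 0.414% (SD, n = 3) in naive H1944 libraries and 5.66 ± 0.190% and 5.64 ± 0.0621% (n = 3 each) in the low and high gates. Over all genes 5457 of 13621 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 2916 higher and 2541 lower, and 1239 of the higher and 480 of the lower changed at least 2-fold. The count was 3482 when all 28 libraries of both lines shared 1 fit.

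TGF-β1 shifted H1944 from an epithelial to a mesenchymal profile, and of the 4 comparisons with naive cells the most genes passed the test here. Such counts do not rank the shift between the lines. In simulated counts the test recovered 79.2% of 2-fold changes in this comparison and 33.3% in A549 under TGF-β1. FN1 rose from 7.41 to 7496 ± 800.2 CPM (SD, n = 6; 10.02 ± 0.13). The collagenase MMP2 rose from 0.453 to 1358 CPM (11.38 ± 0.18), and COL1A1 from 9.95 to 3748 CPM (8.83 ± 0.15). CDH2 (6.65 ± 0.15), SNAI2 (6.62 ± 0.36), VIM (3.33 ± 0.11) and ZEB1 (2.25 ± 0.12) rose, and CDH1 (−4.36 ± 0.11) and EPCAM (−2.93 ± 0.16) fell. MMP2 had 9 naive counts (ratio 2705, 95% counting interval 1425 to 5917). SNAI2 had 5 (ratio 106.1, interval 45.12 to 328.5). The SE of both understates the uncertainty. The mucin MUC5B fell from 2068 CPM to 2 counts over the 6 treated libraries, a ratio of 16020 with a 95% counting interval of 4435 to 132300. The tyrosine catabolism enzyme HPD fell from 2177 to 4.91 CPM, and the calprotectin subunit S100A9 fell from 697 to 2.89 CPM. EZH2 (−0.20 ± 0.10) and CD44 (0.04 ± 0.07) did not pass the test.

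TGF-β target genes rose in 28 of 32 and fell in 1 in H1944 under TGF-β1 (camera adjusted p = 5.53e-53, and adjusted p = 0.00301 with an estimated correlation). Mesenchymal genes rose in 24 of 28 and fell in 1 (adjusted p = 4.42e-32, and adjusted p = 0.00301 with an estimated correlation). Collagens, laminins and matrix enzymes rose in 39 of 45 and fell in 4 (adjusted p = 1.06e-26, and adjusted p = 0.00641 with an estimated correlation). All 3 pairs of counts were the same adjusted over the list alone. Markers of fibroblasts, another cell type, rose in 9 of 11 and fell in 2, likewise adjusted over the list alone (median 6.57; adjusted p = 3.24e-08, but adjusted p = 0.0509 with an estimated correlation). Their summed level was 860 ± 24.0 CPM (SD, n = 3) in naive cells, 4122 ± 256 CPM (n = 3) in the low and 4737 ± 304 CPM (n = 3) in the high gate, of which COL1A1 made 4052 CPM. Integrins rose in 14 of 16 and fell in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.00819 with an estimated correlation). ITGAV (4.02 ± 0.10) and ITGA5 (3.88 ± 0.11) were among them. Epithelial genes fell in 33 of 39 and rose in 4 (33 and 4 adjusted over the list alone; adjusted p = 0.0137 with an estimated correlation), although CLDN1 rose (3.43 ± 0.12). Gut and liver genes fell in 13 of 17 and rose in 2 (13 and 2 adjusted over the list alone; median −2.81; adjusted p = 0.00301 with an estimated correlation). FGA (−7.34 ± 0.13), FGG (−7.30 ± 0.13) and CPS1 (−3.51 ± 0.08) were among the lower. Lung alveolar and secretory genes fell in 12 of 18 and rose in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.00641 with an estimated correlation). NRF2 targets fell in 24 of 31 and rose in 4 (24 and 4 adjusted over the list alone; adjusted p = 0.00819 with an estimated correlation). GPX2 (−6.36 ± 0.13) and AKR1B10 (−2.48 ± 0.07) were among them. Ribosomal protein genes fell in all 75 (75 adjusted over the list alone; adjusted p = 2.07e-27, but adjusted p = 0.0844 with an estimated correlation). Replication-dependent histone genes fell in 46 of 50 (47 adjusted over the list alone; adjusted p = 5.02e-07, but adjusted p = 0.425 with an estimated correlation). Proliferation genes fell in 36 of 60 and rose in 5 (37 and 5 adjusted over the list alone; adjusted p = 0.00156, but adjusted p = 0.497 with an estimated correlation). The replication licensing genes MCM2 (−1.43 ± 0.10) and MCM6 (−1.34 ± 0.10) were among the lower. The mitochondrial share of counts was 4.99 ± 0.277% (n = 3) in the low and 5.02 ± 0.703% (n = 3) in the high gate. By edgeR's quasi-likelihood test 8681 of 13621 genes passed an adjusted p of 0.05, 4372 higher and 4309 lower.

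The lists of genes called under the 2 treatments overlapped within each line. Of the genes called against naive cells, 1956 rose under both GSK126 and TGF-β1 in H1944, where independent lists of these sizes share 936, and 1788 fell under both, where independent lists share 804. In A549 447 rose (56.4 for independent lists) and 431 fell (73.2) under both. Both comparisons used the same naive libraries, and 3 naive libraries cannot be divided into sets of at least 2. In 20 simulations of unchanged groups against them at most 1 gene was shared per direction. Unchanged groups yield few calls, so this number cannot show what shared naive libraries add where genes do change. Across genes, which are not independent replicates, the covariance of the log2 changes was 0.917 in H1944 beside 0.0496 in the simulations, a difference of 0.867, and 0.299 in A549 beside 0.267, a difference of 0.0315. The correlation was 0.640 in H1944 beside 0.569 (range 0.538 to 0.599) in the simulations, but 0.319 in A549 beside 0.551 (0.533 to 0.568), lower than for unchanged groups. Between the lines, which shared no library, 465 genes rose (148 for independent lists) and 265 fell (110) in both under GSK126, and 1175 rose (449) and 1516 fell (685) in both under TGF-β1. All of these comparisons set sorted cells against unsorted naive ones, so the overlaps within and between the lines hold any effect of sorting as well.

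The direct comparison of the treatments, in which all cells had been sorted, separated TGF-β1 from GSK126 in both lines. In A549 the collagen COL22A1 was higher under TGF-β1, at 1274 against 5.65 CPM, and LCE3E, of the cornified envelope, was at least 141-fold higher, with 0 counts in the GSK126 libraries. MUC5AC (−8.14 ± 0.49), AGR2 (−6.91 ± 0.37) and MUC5B (at 1.48 against 283 CPM) were lower. In H1944 MMP2 (7.90 ± 0.10), the growth factor PDGFB (7.42 ± 0.17) and the scaffold gene KANK4 (9.38 ± 0.29) were higher under TGF-β1, and FGA (−7.88 ± 0.12) and SLC51B, a bile acid transporter subunit (−8.02 ± 0.32), were lower. By edgeR's quasi-likelihood test at an adjusted p of 0.05, 3907 of 19842 genes differed in A549, 1590 higher and 2317 lower under TGF-β1, with a median of all genes of 0.19, and 8685 of 13621 differed in H1944, 4310 higher and 4375 lower. The A549 count was 2207 without the GSK126 high library B, 2495 with no filter on low counts and 6042 with limma-voom.

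The comparison of the gates asked which genes accompany a high reporter among cells given the same treatment. In H1944 under GSK126, cells of the high gate had more mesenchymal, TGF-β-responsive and matrix transcripts, together with KRT19 and KRT7. VIM, an intermediate filament of mesenchymal cells, stood at 337 ± 54.9 CPM (SD, n = 3) in the high and 178 ± 25.6 CPM (n = 3) in the low gate (0.93 ± 0.11). The smooth muscle gene TAGLN (1.59 ± 0.16), TGFBI (1.04 ± 0.10) and FN1 (0.57 ± 0.09) were higher. The epithelial genes KRT19 (25.5 against 0.751 CPM, 5.02 ± 0.36) and KRT7 (1.41 ± 0.11) were also higher in the high gate, whereas CDH1 fell by 0.64 ± 0.11 on the log2 scale. The antioxidant gene GPX3 had 119 counts in the high and 3 in the low gate (ratio 44.4, 95% counting interval 14.8 to 218). RARRES1 (4.45 ± 0.54) and PLTP (4.39 ± 0.63) were higher, each on 4 counts in the low gate (95% counting intervals of the ratio 9.17 to 91.3 and 8.19 to 82.1). KRT19 had 8 counts there (interval 16.8 to 78.6). The chemokine CXCL12 (−1.48 ± 0.35), GUCY2C (−1.21 ± 0.31) and GSTA1 (−1.20 ± 0.23) were lower.

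Of 45 collagens, laminins and matrix enzymes 18 were higher and 0 lower in the high GSK126 gate of H1944 (29 and 0 adjusted over the list alone; camera adjusted p = 8.67e-19, and adjusted p = 0.00554 with an estimated correlation). COL7A1 (1.13 ± 0.10) and COL4A1 (0.82 ± 0.09) were among them. TGF-β target genes were higher in 14 of 32 and lower in 0 (20 and 2 adjusted over the list alone; adjusted p = 6.08e-15, and adjusted p = 8.71e-04 with an estimated correlation). Mesenchymal genes were higher in 9 of 28 and lower in 0 (13 and 0 adjusted over the list alone; adjusted p = 1.60e-09, and adjusted p = 0.00413 with an estimated correlation). The mesenchymal glioblastoma genes, the class for which the reporter was designed, were higher in 16 of 48 and lower in 0 (23 and 1 adjusted over the list alone; adjusted p = 2.04e-14, and adjusted p = 0.0272 with an estimated correlation). Epithelial genes were higher in 8 of 39 and lower in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.0406 with an estimated correlation). Replication-dependent histone genes were higher in 20 of 50 and lower in 0 (42 and 0 adjusted over the list alone; adjusted p = 8.83e-20, but adjusted p = 0.0899 with an estimated correlation). H1-5 (0.66 ± 0.10) was among them. Interferon-stimulated genes were higher in 3 of 44 and lower in 0 (3 and 0 adjusted over the list alone; median 0.22; adjusted p = 0.00293, and adjusted p = 0.0420 with an estimated correlation). Fibroblast markers were higher in 2 of 11 and lower in 0 (3 and 0 adjusted over the list alone; median 0.71; adjusted p = 0.00208, but adjusted p = 0.0899 with an estimated correlation). Proliferation genes were higher in 5 and lower in 5 of 60 (6 and 6 adjusted over the list alone; adjusted p = 0.946). Of 13621 genes 1011 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 527 higher and 484 lower, of which 109 and 13 changed at least 2-fold. With the replicate letter of each treatment as a block 1670 genes passed. The count was 368 without the low library B, 575 without the high library A, 672 without the high library C. It was 588 with a stricter filter and 557 with no filter. From the 6 libraries alone it was 459 and 57 in the fit of all 28 libraries.

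**Figure D3:**
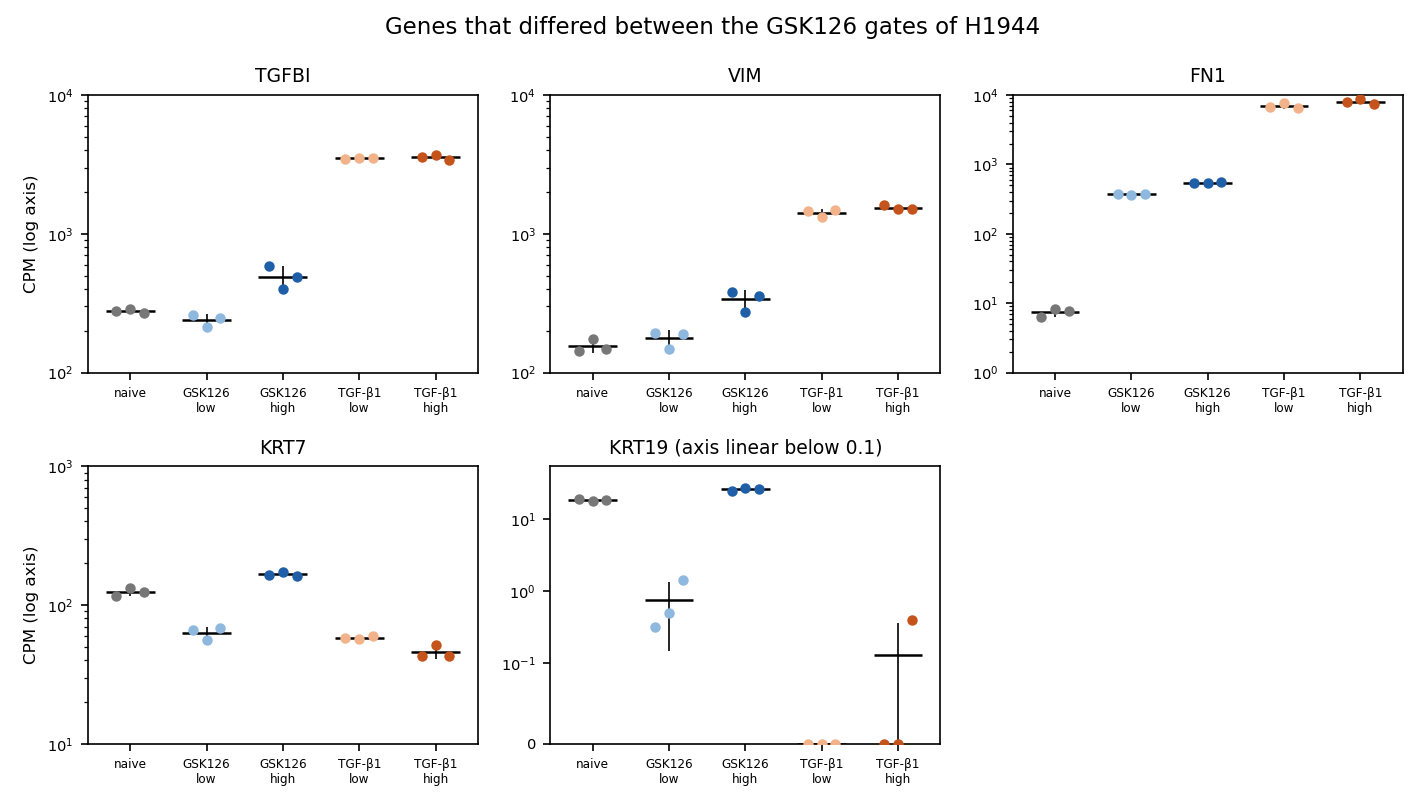
Levels (CPM) of 5 genes in each H1944 library, by treatment and gate. Points are libraries, horizontal bars are means and vertical bars are 1 SD, on log axes that differ between panels; the KRT19 panel is linear below 0.1. KRT19 was at 25.5 CPM in the high and 0.751 CPM in the low GSK126 gate, and all 5 genes were higher in the high than in the low GSK126 gate.

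In H1944 under TGF-β1 the gates differed by few genes beside the reporter. The cytokine IL11 (86.6 against 49.4 CPM, 0.83 ± 0.15) was higher in the high gate. The fibrinogen chains FGG (−2.04 ± 0.40) and FGB (−1.67 ± 0.34), the adhesion molecules CEACAM5 (−1.60 ± 0.30) and CEACAM6 (−1.16 ± 0.24), the mucin MUC16 (−0.79 ± 0.16) and CPS1 (−0.48 ± 0.10) were among the lower. Gut and liver genes were lower in 3 of 17 and higher in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 9.31e-05, and adjusted p = 0.0152 with an estimated correlation). TGF-β target genes were higher in 2 of 32 and lower in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.00126, and adjusted p = 0.0428 with an estimated correlation). VIM (0.14 ± 0.10) and CDH1 (−0.90 ± 0.21) did not pass the test. By edgeR's quasi-likelihood test 11 of 13621 genes passed an adjusted p of 0.05, 2 higher and 9 lower. The count was 0 without the high library A, 1 without the low library A, 2 without each of the high libraries B and C and the low library C. It was 21 with limma-voom, 7 with a stricter filter, 58 from the 6 libraries alone and 0 in the fit of all 28 libraries. A regrouping of these 6 libraries that mixed the gates gave 89, so chance was not excluded. Both of the genes higher here were also higher in the high gate under GSK126 (Fisher's exact test, 2-sided, p = 0.00149), and 4 of the 9 lower genes were lower there too (p = 1.72e-04). This test takes genes as independent, and both sets of calls came from the same fit. Its p-values therefore cannot show that a gate effect was repeated between the treatments.

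The gate effect was also compared between the treatments in H1944. KRT7 (−1.74 ± 0.17), TAGLN (−1.54 ± 0.21) and VIM (−0.80 ± 0.15) had a smaller gate effect under TGF-β1 than under GSK126. SEMA6A (1.77 ± 0.39) and MECOM (0.82 ± 0.20) had a larger one under TGF-β1. In edgeR's quasi-likelihood test of the difference 81 of 13621 genes passed an adjusted p of 0.05, 19 with a larger and 62 with a smaller effect under TGF-β1. Without the GSK126 libraries high A, low B and high B the count was 51, 23 and 233. Without the TGF-β1 libraries low A, B and C it was 28, 41 and 29, and without the TGF-β1 libraries high A, B and C it was 31, 23 and 35. It was 361 with the replicate letter of each treatment as a block, 193 with limma-voom, 126 with DESeq2, 43 with no filter, 29 with a stricter filter and 2 in the fit of all 28 libraries.

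By edgeR's quasi-likelihood test 0 genes passed between the A549 gates under either treatment, while DESeq2 and limma-voom called 17 and 1438 under TGF-β1. With the replicate letter of each treatment as a block 149 genes passed under GSK126 and 980 under TGF-β1. Under GSK126 KRT19 stood at 555 ± 119.9 CPM (SD, n = 2) in the high and 461 ± 52.3 CPM (n = 3) in the low gate (0.46 ± 0.26), and VIM did not pass either (0.38 ± 0.29). Under TGF-β1 VIM stood at 2012 ± 332 CPM (n = 3) and 1946 ± 5.99 CPM (n = 2; 0.08 ± 0.29). Under TGF-β1 camera placed the TGF-β target genes higher in the high gate (0 of 34 passed over all genes and 5 rose adjusted over the list alone; adjusted p = 8.96e-12, but adjusted p = 0.408 with an estimated correlation). Under GSK126 it placed 13 lists higher and 2 lower, and the smallest adjusted p was 0.620 with an estimated correlation. These included replication-dependent histone genes (0 of 45 passed, median 0.49, adjusted p = 5.83e-15) and ribosomal protein genes (0 of 75 passed, median 0.31, adjusted p = 1.36e-09). Reads over silent olfactory receptor genes stood at 24.6 ± 26.3 CPM (n = 2) in the high and 82.9 ± 8.81 CPM (n = 3) in the low GSK126 gate.

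Of 19842 genes 0 passed edgeR's quasi-likelihood test between the A549 gates under GSK126, where 980 had an unadjusted p under 0.05 and DESeq2 and limma-voom each called 0. By edgeR 0 passed under TGF-β1, where 198 had an unadjusted p under 0.05, DESeq2 called 17 and limma-voom 1438. For the difference of these gate effects 0 genes passed by edgeR, with 464 at an unadjusted p under 0.05, 5 by DESeq2, 3 by limma-voom and 38 with the block. In simulated counts with the spread of these libraries the same test recovered 3.95% of genes changed 2-fold between the GSK126 gates and 9.23% between the TGF-β1 gates of A549, against 62.5% and 67.9% in H1944. Under TGF-β1, 62 genes passed without the 2 libraries of highest background, 6 without the high library B and 1 without the low library C. There were 9 with the background as a covariate, 12 in the fit of all 28 libraries, and 3 either with no filter or with expressed coding genes only. Under GSK126, 18 passed from the 5 libraries alone.

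The last set of comparisons asked whether an effect differed between the lines. Under GSK126 the change of COL12A1 (5.13 ± 0.27), the tight junction gene CLDN2 (5.10 ± 0.34) and FN1 (4.04 ± 0.30) was higher in H1944 than in A549. The change of FBN1 (−4.60 ± 0.20) and of the peptidase gene ANPEP (−5.47 ± 0.41) was lower in H1944. Under TGF-β1 the change of FN1 (7.39 ± 0.32) and CEACAM6 (7.68 ± 0.29) was higher in H1944, and that of PRIMA1 (−8.96 ± 0.71), a membrane anchor of acetylcholinesterase, and of complement C3 (−4.84 ± 0.28) was lower. By edgeR's quasi-likelihood test of the difference 1777 of 17918 genes passed an adjusted p of 0.05 under GSK126, 1105 higher and 672 lower in H1944 than in A549 with a median of all genes of 0.13. Under TGF-β1 3580 passed, 1890 higher and 1690 lower. The GSK126 count was 1174 with the low gate alone and 2893 with limma-voom, and the TGF-β1 count was 6118 with limma-voom.

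The gate effect under GSK126 was higher in H1944 than in A549 for 5 of 17918 genes, among them KRT19 (4.52 ± 0.43), the ubiquitin hydrolase UCHL1 (2.12 ± 0.34), the elongation factor EEF1A2 (1.60 ± 0.30) and ZNF469 (3.92 ± 0.75). ZNF469 had 3 counts in the low and 66 in the high gate of H1944 (ratio 24.6, 95% counting interval 8.06 to 122.4). Under TGF-β1 the glucuronidation enzyme UGT2B4 alone passed (2.37 ± 0.34). The count of 5 was 1 without the H1944 low library A, 2 without each of the H1944 libraries high A, high B and low B, 3 without the A549 low library B or the H1944 high library C. It was 8 with RLE size factors, 27 with no filter, 9 with expressed coding genes, 12 with the background covariate, 29 without the 2 libraries of highest background and 15 with DESeq2. With the replicate letter of each treatment as a block it was 44. The count of 1 was 2 with RLE size factors, with no filter or with expressed coding genes. It was 4 with the background covariate, 19 without the 2 libraries of highest background, 3 without the A549 high library B, 8 with DESeq2, 116 with limma-voom and 119 with that block.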

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

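The tests of spread, of background reads and of A549 RNA, and the test of loss in the low gate, were chosen only after the result was seen; the splits that follow the pairs were chosen after it too, and the other splits and the left-out libraries before.

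The effect of treatment differed between the lines for 1777 genes under GSK126 and 3580 under TGF-β1. For GSK126 the fit of the compared libraries gave 1819 genes, and over splits that kept the paired H1944 libraries together the highest other gave 2873. With the real grouping included 3 of 100 were as large, and the 2 larger splits kept the real grouping of H1944 and regrouped A549 alone. The 85 that kept neither grouping reached 0. These splits exchange treated and naive libraries within a line, so they also remove that line's own treatment effect. They cannot decide whether the difference between the lines arose by chance. For TGF-β1 the fit of the compared libraries gave 3642 genes against 3096 as the highest other, with 1 of 100 as large. Chance remains undecided there for the same reason. The split with 3096 genes kept the real grouping of A549, and those that kept neither grouping reached at most 0.

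The gate effect differed between treatments for 81 genes in H1944. Chance was not excluded, and the splits could not decide it. In the fit of the compared libraries without a block 66 genes passed with the real grouping. Over the 80 splits that parted all GSK126 pairs the highest other had 387. That split kept both real pairs of gates, with high and low exchanged under 1 treatment. Of the 80, 16 were as large, the real grouping included. All 16 kept the real GSK126 gates, and with them the gate effect of that treatment. The 54 that kept neither pair of gates reached at most 3. With the replicate block by culture 361 genes passed, for which no splits were run.

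Between the lines the gate effect under GSK126 differed for 5 genes, among them KRT19 (4.52), UCHL1 (2.12), EEF1A2 (1.60) and ZNF469 (3.92, on 3 counts in the H1944 low gate), and under TGF-β1 for 1, UGT2B4 (2.37). Fewer genes passed between the A549 gates under GSK126 than between those of H1944. By edgeR 0 passed in A549, with 980 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom, but 149 with the replicate block by culture. Whether background reads reduced the count remains open: the highest count over 3 settings against background was 0, but the test recovered only 3.95% of simulated 2-fold changes there, and the libraries left out in 1 setting were not in this comparison. A larger spread that hides a like effect also remains open: over 990 genes called in H1944, with folds taken in the H1944 direction, the median log2 change was 0.216 in A549 and 0.505 in H1944. It was 0.0317 without the high library B and 0.406 without the high library A. The genes higher in H1944 had a median of 0.374 in A549 against 0.578, and the lower ones 0.0876 against 0.469. The 100 that were at least 2-fold higher had 0.107 (bootstrap 95% interval over genes −0.0958 to 0.272) against 1.40, which goes against a like effect for these. However, this interval leaves out the spread between libraries, with a median standard error per gene of 0.447 in A549. Choosing genes by their H1944 change also raises the H1944 values. A smaller separation of the A549 gates could still contribute, as the reporter differed by 1.02 in A549 and 1.83 in H1944.

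For the genes higher in the high gate of H1944 under GSK126 as a set, A549 RNA in those libraries is unlikely as the source. The 13 A549-only genes allowed a median of 1.24% and at most 20.8%, where the 527 higher genes would need a median of 35.9%. For single genes abundant in A549 this median cannot decide. KRT7, for example, stood at 3579 and 4378 CPM in the A549 high GSK126 libraries. The first choice of marker level left 1 gene, and the level was lowered to 20 CPM after this was seen. That 1 library decides the count remains open, as 368 genes passed without the low library B. Loss in the low gate, rather than gain in the high gate, might account for part: 31.2% of the 109 genes at least 2-fold higher, 34 of them, were lower in the low gate than in naive cells, and 82 were higher in the high gate than in naive cells.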

How the results depend on the processing

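All tests of the added alternatives, which are coding genes only, the background covariate and the fit without 2 background-rich A549 libraries, were chosen only after the result was seen. Counts are named below where they moved by more than 1.5 times; the cause was not tested.

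Against naive cells, the A549 GSK126 count of 1363 was 2205 with coding genes only, 2673 with the background covariate, 2674 without the background-rich libraries, 873 with the low gate only, 3412 with limma-voom, 2281 with DESeq2, 2257 from the compared groups and 2838 with all 28 libraries, and 676 to 1745 with a library left out (676 without GSK126 high B, 871 without naive B). The A549 TGF-β1 count of 3821 was 2433 with the low gate only, 7887 with limma-voom and 2750 to 4580 with a library left out. In H1944 the GSK126 count of 5457 was 3482 with all 28 libraries and 4026 to 5727 with a library left out, and the TGF-β1 count of 8681 was 7681 to 8632 with a library left out.

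Between treatments, the A549 count of 3907 was 2495 with no filter, 6042 with limma-voom and 2207 (without GSK126 high B) to 4364 with a library left out. The H1944 count of 8685 was 8367 to 8753.

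Between the A549 gates, the GSK126 count of 0 was 18 from the compared groups and 0 with each library left out. The TGF-β1 count of 0 was 3 with no filter, 3 with coding genes only, 9 with the covariate, 62 without the background-rich libraries, 1438 with limma-voom, 17 with DESeq2, 12 with all 28 libraries and 0 to 6 with a library left out (6 without high B, 1 without low C). The difference of these effects, 0, was 2 without the background-rich libraries, 3 with limma-voom, 5 with DESeq2, 1 from the compared groups and 0 with each library left out.

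Between the H1944 gates, the GSK126 count of 1011 was 557 with no filter, 588 with the stricter filter, 459 from the compared groups, 57 with all 28 libraries and 368 to 1470 with a library left out (575 without high A, 368 without low B, 672 without high C). The TGF-β1 count of 11 was 7 with the stricter filter, 21 with limma-voom, 58 from the compared groups, 0 with all 28 libraries and 0 to 9 with a library left out (1 without low A, 0 without high A, 2 without high B, low C or high C). The difference of 81 was 43 with no filter, 29 with the stricter filter, 193 with limma-voom, 126 with DESeq2, 2 with all 28 libraries and 23 to 233 with a library left out (GSK126 high A 51, low B 23, high B 233; TGF-β1 low A 28, high A 31, low B 41, high B 23, low C 29, high C 35).

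Between the lines, the GSK126 count of 1777 was 1174 with the low gate only, 2893 with limma-voom and 1367 to 1976 with a library left out, and the TGF-β1 count of 3580 was 6118 with limma-voom and 3034 to 4383 with a library left out. The gate count under GSK126, 5, was 8 with RLE, 27 with no filter, 9 with coding genes only, 12 with the covariate, 29 without the background-rich libraries, 15 with DESeq2 and 1 to 7 with a library left out (A549 low B 3; H1944 low A 1, high A 2, low B 2, high B 2, high C 3). Under TGF-β1 the count of 1 was 2 with RLE, 2 with no filter, 2 with coding genes only, 4 with the covariate, 19 without the background-rich libraries, 116 with limma-voom, 8 with DESeq2 and 1 to 3 with a library left out (3 without A549 high B).

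With treatment and letter as a replicate block by culture, the H1944 gate counts were 1670 under GSK126 and 28 under TGF-β1 and their difference 361, the A549 gate counts were 149 and 980 and their difference 38, and the gate counts between the lines were 44 and 119. With the letter alone as the replicate block, the latter were 3 and 2; it moved no other count by more than 1.5 times. Outside the H1944 GSK126 gates the letters were not taken as pairs: same-letter correlations were 0.054, 0.139 and −0.022 for the H1944 TGF-β1 gates, 0.160 and 0.084 for the A549 GSK126 gates, and 0.164 and 0.521 for the A549 TGF-β1 gates, which have 2 pairs each. In A549 their median was 0.16 beside −0.12 for gates of other letters, so pairs are not excluded there.

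Of the lists called by camera, 19 in A549 under GSK126 became 3 with an estimated correlation and 9 with fry, 18 under TGF-β1 became 6 with an estimated correlation, 15 in H1944 under GSK126 became 2 and 17 under TGF-β1 became 10. Between the gates, 15 in A549 under GSK126 became 0 and 0 with fry, 5 under TGF-β1 became 0 and 0, 14 in H1944 under GSK126 became 6 with an estimated correlation, and 6 under TGF-β1 became 2 and 2.

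Over 439 pairs of a named gene and a comparison, 304 were called, and 246 of these kept the call in every setting. Only mVenus in H1944 under GSK126 against naive cells reversed, to −0.67 with the low gate only.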

Other observations

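The tests of ribosomal protein share, the splits that follow the pairs and the splits between sorted groups were chosen only after the result was seen; the other splits against naive cells were chosen before.

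In H1944 under GSK126 several genes stood near or above their naive level in the high gate and below it in the low gate. KRT19 was at 25.5 ± 1.39 CPM (SD, n = 3) in the high gate, 0.751 ± 0.602 CPM (n = 3) in the low gate and 18.1 ± 0.728 CPM (n = 3) in naive cells. GPX3 was at 12.9 ± 1.68, 0.295 ± 0.322 and 4.39 ± 1.36 CPM, and KRT7 at 167 ± 4.59, 63.2 ± 6.24 and 124 ± 8.32 CPM.

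Some genes moved alike in all 4 comparisons with naive cells. HLA-DMB, of MHC class II peptide loading, fell in A549 under GSK126 (−3.89 ± 0.53) and TGF-β1 (−3.72 ± 0.48) and in H1944 (−2.35 ± 0.15 and −6.32 ± 0.26). The 8 MHC class II genes tested in A549 under GSK126 had a median of 1.63, and 0 rose and 1 fell (4 and 1 adjusted over the list alone). OAS1, an antiviral sensor, fell likewise (−1.45 ± 0.21, −2.22 ± 0.21, −1.43 ± 0.09 and −1.90 ± 0.10), but interferon-stimulated genes as a list did not: in H1944 under GSK126 22 of 44 rose and 6 fell (camera adjusted p = 0.0484, but adjusted p = 0.164 with an estimated correlation), and camera called the list in none of the other 3 comparisons. JARID2, a cofactor of the EZH2 complex, rose in each (0.96 ± 0.21, 2.37 ± 0.22, 0.81 ± 0.11 and 2.40 ± 0.11).

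Ribosomal protein genes were lower in treated sorted libraries than in unsorted naive ones, and sorting could lie behind this. In H1944 their share of counts was 1.86 ± 0.148% (n = 6) under TGF-β1 and 3.26 ± 0.162% (n = 6) under GSK126, both sorted, beside 4.77 ± 0.355% (n = 3) in naive cells. The shares ran from 1.69 to 2.03% and from 3.10 to 3.44%, and the exact permutation p with the paired GSK126 libraries kept together was 0.0217, the smallest possible. Sorting alone is thereby excluded as the whole cause only if it acted alike on both treatments, which was not tested. The TGF-β1 libraries must also not be pairs: with 3 cultures per treatment the exact permutation p was 0.1, the smallest possible. A part shared by both treatments remains open. In A549 the shares were 4.22 ± 0.688% (n = 5) and 4.29 ± 0.431% (n = 5) beside 5.87 ± 0.808% (n = 3), with an exact permutation p = 0.889, and sorting alone remains open.

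For 3 comparisons with naive cells chance can be excluded only if their same-letter gates are not pairs. If they are pairs, too few splits remain for a share under 0.05. In A549 this stays open, as same-letter gates had a median correlation of 0.16 beside −0.12 for other letters. The real grouping gave 2148 genes in A549 under GSK126 and 3473 under TGF-β1, the highest other of 56 splits 0 and 1. In H1944 under TGF-β1 it gave 8740, the highest other of 84 splits 0. In H1944 under GSK126 only 10 splits keep the paired libraries together, too few for a share under 0.05; the real grouping gave 4430 and the highest other 0. Between the treatments chance can be excluded only under the same proviso, which stays open in A549. The real grouping gave 4989 genes in A549 against 0 as the highest other of 100 splits. In H1944 it gave 7765 against 0 over 46 that keep the GSK126 pairs together. In each of these 6 results, H1944 under GSK126 included, only 1 split, the real grouping, was as large. Between the H1944 gates the splits are too few for a share under 0.05. Under GSK126 the real grouping gave 459 genes and the highest other of 4 that part all pairs 0, with 1 as large. Under TGF-β1 the real grouping gave 58 genes, and of 10 splits 2 were as large. The highest other, which mixed the gates, gave 89, so the real gates were not the most extreme grouping. The letters may mark technical replicates of a single culture, which the labels do not settle.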
